A study of Drosophila melanogaster with 4 samples.

How the data were processed

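Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map trimethylation of histone H3 at lysine 4 (H3K4me3), a mark known from textbooks to lie at active promoters, in whole embryos of wild-type Drosophila melanogaster of the Oregon-R strain. Embryos were staged at 14 to 16 h. Per the labels' protocols, embryos were fixed with 1.8% formaldehyde, and the chromatin was incubated with the antibody for 15 h. One commercial antibody to H3K4me3, of lot 2, was used for both immunoprecipitations. The 4 samples fall into 2 groups, with 2 H3K4me3 ChIP samples and 2 Input samples (chromatin that was not immunoprecipitated). The labels do not say whether the replicates came from separate embryo collections, so the spread between them may be technical.

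Each ChIP replicate has its own list of enriched regions, and the series has a further list for the replicate set, called the combined list here. The Input samples have no list of their own and entered only as the background of the authors' calls. Per the labels, the Input sample numbered 2 served as input for the list of ChIP replicate 1 and the Input sample numbered 1 for that of ChIP replicate 2, so the replicate numbers of the 2 groups do not name matching samples. Bowtie 0.12.7, a short-read aligner, is named in the submitters' processing notes. Coordinates are on FlyBase release 5, per the file headers. The region caller, its thresholds, the scale of the score and the way in which the combined list was made are not given in the sources used here. Each region has a start, an end and 1 score; the deposited score is positive for rows typed as enrichment and negative for rows typed as depletion. Because the scale of the authors' score is not given, scores were compared as differences and ranks and never as folds. Differences between lists take their scores to be on a common scale, which is not known. Read counts per library are not given in these lists, so the depth is unknown and no value could be weighted by it.

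Rows typed as enrichment were used throughout, and rows typed as depletion were set aside. No list contained regions that overlapped each other. Regions of different lists were called shared when they overlapped by at least 1 base. The overlap of the replicates was set against 1000 circular shifts of the list of replicate 2 within each chromosome (one-sided), which keep the widths and the spacing of its regions. The chance level of support by score quartile and of regions of at least 10 kb was taken from 1000 such shifts of the other replicate (two-sided). Scores were compared over region pairs in which each region was the other's largest overlap. Shared and unshared regions of a replicate were compared by a two-sided permutation test of the difference of medians with 100000 resamples, and also against 1000 shifts of the other replicate. The comparisons by score quartile, of regions of at least 10 kb and of shared against unshared regions by shifts were chosen after seeing the data. Region counts on the 6 chromosome arms (2L, 2R, 3L, 3R, 4 and X) were tested against each arm's share of the sequence length with an exact binomial test (two-sided), with Benjamini-Hochberg adjustment over the 6 arms. Shares carry 95% Wilson intervals and observed-over-expected ratios exact 95% intervals. In all of these tests the regions are the units, and neighbouring regions are not independent, so the p-values and intervals describe these lists and cover counting error only. With 2 replicates of 1 group, no test between conditions was possible. Sequence lengths came from the file headers. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Numba 0.67.0 and Matplotlib 3.10.9 were used.

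The tests were checked on simulated lists of 2000 regions placed on the same arms. A planted difference of 0.5 in the median score was recovered as 0.48. A planted ratio of observed to expected regions on X of 0.74 came out as 0.73. The planted overlap of 60% was made of copied regions, with all others kept apart, so its recovery as 60% was fixed by the design. This recovery checks the counting and does not show that true sharing is recovered where regions also meet by chance. Simulated lists were of equal size, with scores drawn without regard to width, unlike the real lists. An unrelated list gave a p of 0.88 against the shifts. Simulated regions were placed independently along the arms, while the real lists are uneven. These checks therefore do not show how the binomial and shift tests behave on lists with clumped regions.

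The regions named in the text were fixed by rule before the data were examined: the 5 highest scores and the 5 greatest widths of the combined list, and the 5 highest scores of each replicate among regions that met no region of the other. Alternatives to the scores kept, the minimum width, the overlap required, the number of regions, the merging of neighbours and the list used were fixed at the same time. Planned comparisons with transcription start sites, with annotated genomic features and with 21 lists of genes (including markers of embryonic and adult cell types) were not run. They need gene positions on release 5, while the gene table at hand is on release 6, and coordinates were not converted between releases. Regions are therefore given by position and not by gene.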

Results

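H3K4me3 was mapped by ChIP-seq in wild-type Oregon-R embryos staged at 14 to 16 h, late in embryogenesis, in 2 ChIP replicates with 2 Input samples as background. Each replicate has a list of enriched regions, and a combined list covers the replicate set. The design holds 1 stage, 1 genotype and 1 antibody, so the data answer where the mark lay along the genome and how far the replicates shared those positions. Positions are on FlyBase release 5, and no depth per library is known.

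The regions called as enriched in H3K4me3 were mostly a few kilobases wide. The list of replicate 1 held 9260 enriched regions and that of replicate 2 held 4959, a mean of 7109.5 ± 3041 (SD, n = 2). The combined list held 5539. Median region width was 2296 bases in replicate 1, 2823 bases in replicate 2 and 2753 bases in the combined list, whose middle 50% of widths ran from 2218.5 to 3836.5 bases. The narrowest regions were 1301, 1302 and 1001 bases in the same order. Whether the unknown caller set a lower limit of width is not known, so the widths describe the calls. The regions covered 27.4 Mb in replicate 1, 16.4 Mb in replicate 2 and 17.9 Mb in the combined list, or 16.3%, 9.73% and 10.6% of the sequence named in the file headers. The median of the authors' score was lower in replicate 1, at 0.63, than in replicate 2, at 2.21, and was 1.55 in the combined list. The highest scores were 3.07, 4.29 and 3.68. At the low end the replicates' scores were alike, with a 5th percentile of 0.36 in replicate 1 and 0.34 in replicate 2. The replicates' lists were called against different Input samples, and whether their scores share a scale is not known. Wider regions had higher scores, with a Spearman rho between width and score across regions of 0.72 in replicate 1, 0.73 in replicate 2 and 0.75 in the combined list. Regions within a list are not independent replicates, and the difference in number between the replicates has no test.

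**Figure D1:**
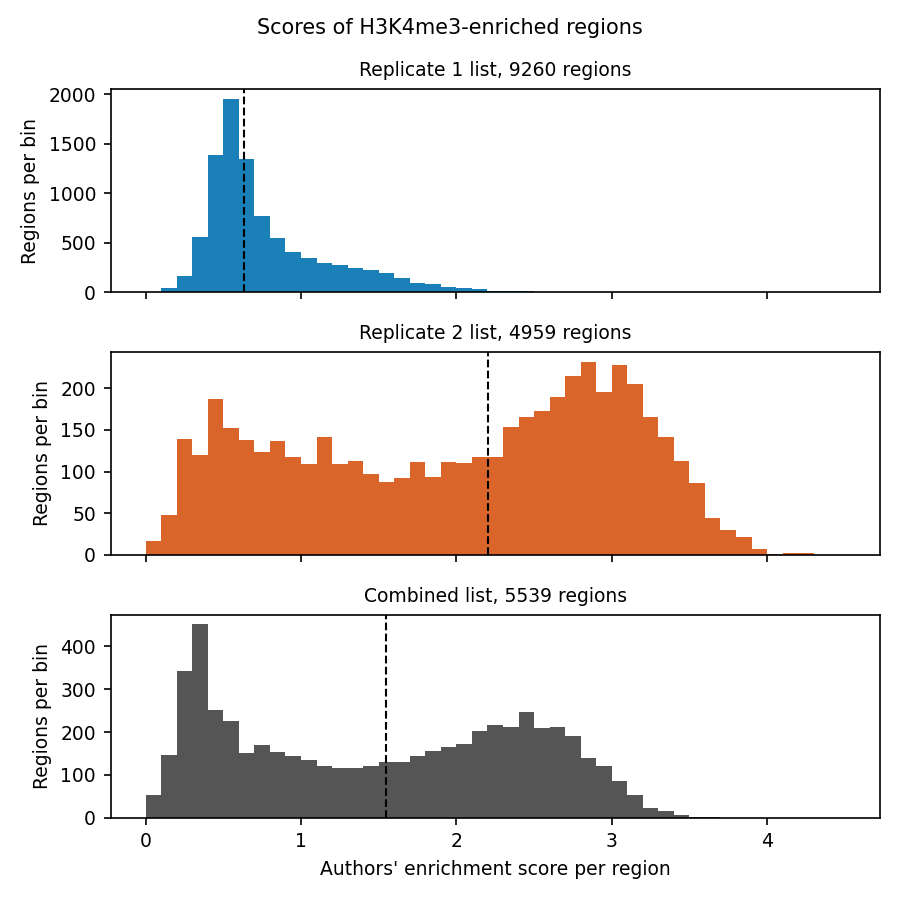
Histograms of the authors' enrichment score per region (x axis, bins of 0.1) against the number of regions per bin (y axis) in the lists of replicate 1, replicate 2 and the replicate set; dashed lines mark the medians, and the y axes differ between panels. Scores of replicate 1 gather around its median of 0.63, while the lists of replicate 2 and of the replicate set spread from near 0 to above 3, with medians of 2.21 and 1.55.

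Most regions of replicate 2 were also present in replicate 1, whereas only about 50% of the regions of replicate 1 were present in replicate 2. Of the 4959 regions of replicate 2, 4328 met a region of replicate 1 (87.3%, Wilson 95% interval 86.3% to 88.2%). Of the 9260 regions of replicate 1, 4632 met a region of replicate 2 (50.0%, 49.0% to 51.0%). Circular shifts of the list of replicate 2 gave means of 39.8% and 23.2%, with highest values of 47.5% and 27.6%. The bases covered in both replicates were 42.9% of those covered in either, against a mean of 9.26% for the shifts. Each of these 3 values exceeded all 1000 shifts (one-sided permutation of positions, p = 0.001, the smallest that they can give). When replicate 1 was reduced to its 4959 highest scores, 71.5% of its regions met replicate 2 and 68.6% of those of replicate 2 met replicate 1.

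Support in the other replicate was highest for the regions with the highest scores, but in replicate 1 it did not follow the score over the lower quartiles. In the highest score quartile of replicate 2, 1238 of 1239 regions were shared (99.9%), and in its lowest quartile 757 of 1240 (61.0%), where shifts gave a mean of 34.9%. In the highest quartile of replicate 1, 2244 of 2315 regions were shared (96.9%, against 26.3% for the shifts), and in the third quartile 1210 of 2315 (52.3%, against 25.4%). In its second quartile, with scores from 0.51 to 0.63, the share was 21.3%, inside the central 95% of the shifts (19.7% to 23.4%; two-sided permutation of positions by shifts, p = 0.917, also 0.917 after Benjamini-Hochberg adjustment over 12 such sets). In its lowest quartile the share was 29.5%, above the shifts' mean of 19.7% (permutation by shifts, p = 0.002, the smallest that a two-sided test can give, adjusted p = 0.0024).

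Shared regions had higher scores and were wider than unshared regions of the same replicate. In replicate 1 the median score was 0.92 in the 4632 shared regions and 0.55 in the 4628 unshared regions, and the median widths were 2732 and 1877 bases. In replicate 2 the median score was 2.43 in the 4328 shared regions and 0.61 in the 631 unshared regions, and the median widths were 3008.5 and 2058 bases. All 4 differences gave an adjusted p of 1e-05 in two-sided permutation tests, the smallest that 100000 resamples can give. Wide regions meet another list more often by chance: with the other replicate shifted, the mean width difference was 294.2 bases in replicate 1 and 259.5 bases in replicate 2, and the highest of 1000 shifts gave 536 and 455 bases, below the observed 855 and 950.5 bases. For scores the shifts gave mean differences of 0.05 and 0.26, against 0.37 and 1.82 observed (two-sided permutation by shifts, p = 0.002 for all 4). This comparison with shifts was chosen after seeing the data. With both lists at equal numbers of regions, the width difference in replicate 1 was -10.5 bases, shared minus unshared (permutation test, adjusted p = 0.848).

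At shared positions the replicates ranked regions alike but on different levels of score. Over 4302 matched pairs, Pearson's r of the scores was 0.69 and Spearman's rho 0.74, across regions. The median score was 0.94 in replicate 1 and 2.43 in replicate 2, and 91.5% of the pairs had the lower score in replicate 1. The median difference, replicate 1 minus replicate 2, was -1.37. Region widths had a Spearman rho of 0.66, with medians of 2800.5 bases in replicate 1 and 3018 bases in replicate 2. By arm, the rho of the scores lay between 0.63 on chromosome 4, with 31 pairs, and 0.76 on X, with 745 pairs.

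**Figure D2:**
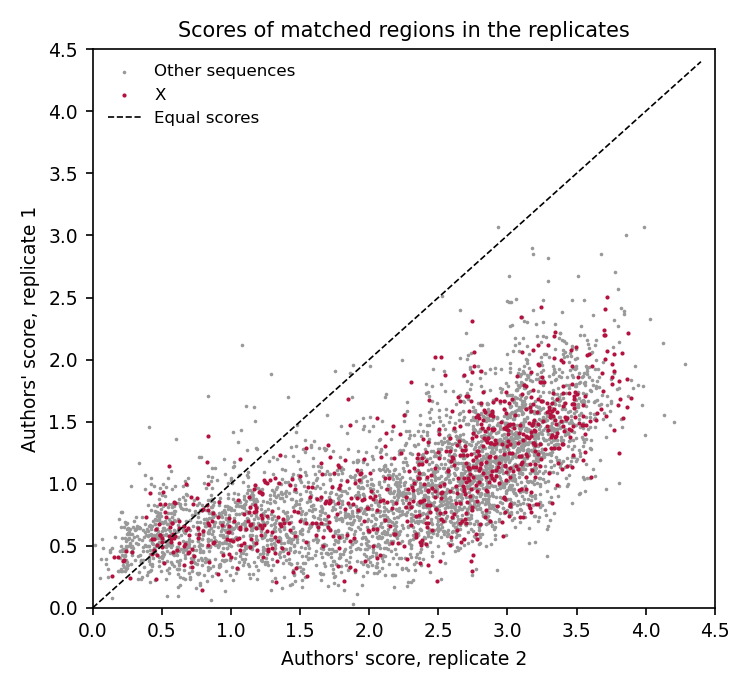
Authors' score of each of 4302 matched regions in replicate 2 (x axis) and replicate 1 (y axis); 1 point is 1 region, red points are on X, grey points on all other sequences, and the dashed line marks equal scores. Scores rise together (Spearman's rho 0.74), and 91.5% of the points lie below the line.

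The combined list held nearly all regions of replicate 2 and about 54.0% of those of replicate 1. It met 4935 of the 4959 regions of replicate 2 (99.5%, Wilson 95% interval 99.3% to 99.7%) and 5005 of the 9260 of replicate 1 (Wilson 95% interval 53.0% to 55.1%). Of its own 5539 regions, 87.2% were met by replicate 1 and 88.8% by replicate 2. Of these, 4305 were met by both replicates (77.7%, 76.6% to 78.8%), 527 by replicate 1 only, 614 by replicate 2 only and 93 by neither (1.68%). Regions met by both had a median score of 1.97 and a median width of 3149 bases. Those met by replicate 1 only had medians of 0.33 and 1467 bases, those met by replicate 2 only 0.39 and 2010.5 bases, and those met by neither 0.31 and 1231 bases. The median of 1231 bases lies below the narrowest region of either replicate's list (1301 and 1302 bases), while the combined list starts at 1001 bases. How far these different lower ends of width account for the unmatched regions was not tested. Among the 1245 combined regions with scores under 0.5, 23.9% were met by both replicates, and among the 1048 with scores of 2 to 2.5, 99.9% were. The combined list comes from the same samples and is not independent evidence for either replicate.

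Among the chromosome arms, the right arm of chromosome 2 (2R) was the richest in H3K4me3 regions and the left arm (2L) among the poorest. In the combined list, 2R held 1123 regions, or 53.1 per Mb, which was 1.17 times the number expected from its length (exact 95% interval 1.11 to 1.23, exact binomial adjusted p = 7.5e-08). The arm 2L held 954 regions, or 41.5 per Mb, with a ratio of 0.91 (0.86 to 0.97, exact binomial adjusted p = 0.00552). By the same exact test, ratios were 0.94 on 3L (1050 regions, adjusted p = 0.0494), 1.05 on 3R (1328 regions, adjusted p = 0.0583) and 0.94 on X (952 regions, 0.88 to 0.99, adjusted p = 0.0456). Chromosome 4, a small and largely heterochromatic chromosome, held 55 regions, with a ratio of 0.90 (exact 95% interval 0.68 to 1.17, adjusted p = 0.479). The binomial tests were two-sided, with Benjamini-Hochberg adjustment over the 6 arms. They take regions as placed independently, while combined counts ran from 10 to 80 per bin of 1 Mb along the large arms. The p-values and intervals are therefore likely too sharp, which matters most for the weaker calls on 2L, 3L and X. Counted by bases covered in place of regions, with no test, ratios were 1.16 on 2R, 1.04 on 3R and 0.98 on X. They were 0.94 on 3L, 0.90 on 2L and 0.74 on 4.

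In the replicates' own lists, the excess on 2R was present in both, with ratios of 1.12 in replicate 1 and 1.18 in replicate 2. By exact binomial tests, the ratio on X was 0.87 in replicate 1 (adjusted p = 2.6e-09) and 0.95 in replicate 2 (adjusted p = 0.228), and the ratio on 4 was 0.62 in replicate 1 (adjusted p = 7.7e-05) and 0.87 in replicate 2 (adjusted p = 0.453). On 2L the ratio was 0.98 in replicate 1 (exact binomial adjusted p = 0.312) and 0.91 in replicate 2 (adjusted p = 0.00559). On 3L it was 1.02 in replicate 1 and 0.96 in replicate 2, so only the call on 2R held in both. Region density, as the mean of the replicates, was 66.9 ± 27.1 per Mb on 2R, 60.2 ± 26.8 on 3R, 58.6 ± 27.5 on 3L, 55.8 ± 26.7 on 2L, 52.5 ± 19.5 on X and 41.4 ± 8.37 on 4 (SD, n = 2). These SDs include the difference in list length between the replicates, and in each replicate 2R had the highest density of the 6 arms.

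**Figure D3:**
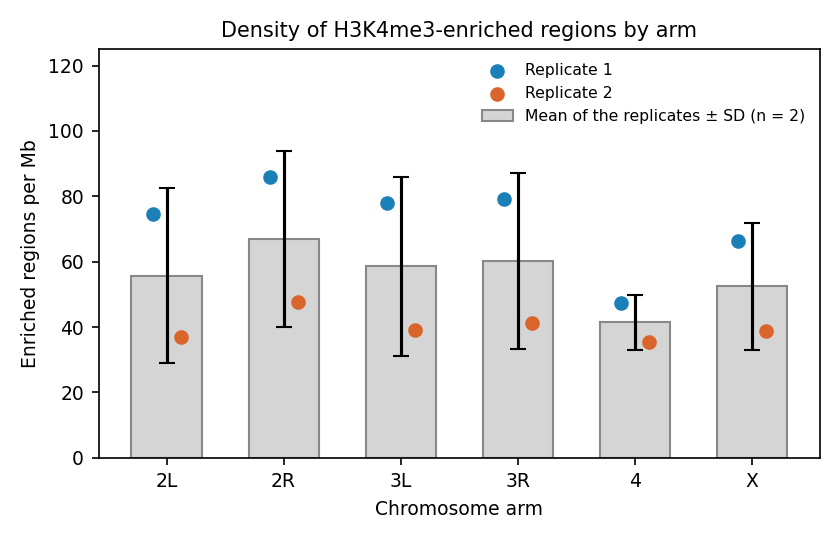
Enriched regions per Mb (y axis, from 0) on each chromosome arm (x axis); grey bars are the mean of the 2 replicates with SD, and blue and orange points are replicates 1 and 2. Both replicates have their highest density on 2R, at 86.1 and 47.8 regions per Mb.

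Along the 5 large arms the density of combined regions was uneven. Over 117 full bins of 1 Mb the median was 46 regions, from 10 on 3L between 23000001 and 24000000 to 80 on 2R between 3000001 and 4000000. The replicates' counts per bin had a Spearman rho of 0.53 and a Pearson r of 0.59, across bins, which are not independent replicates.

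**Figure D4:**
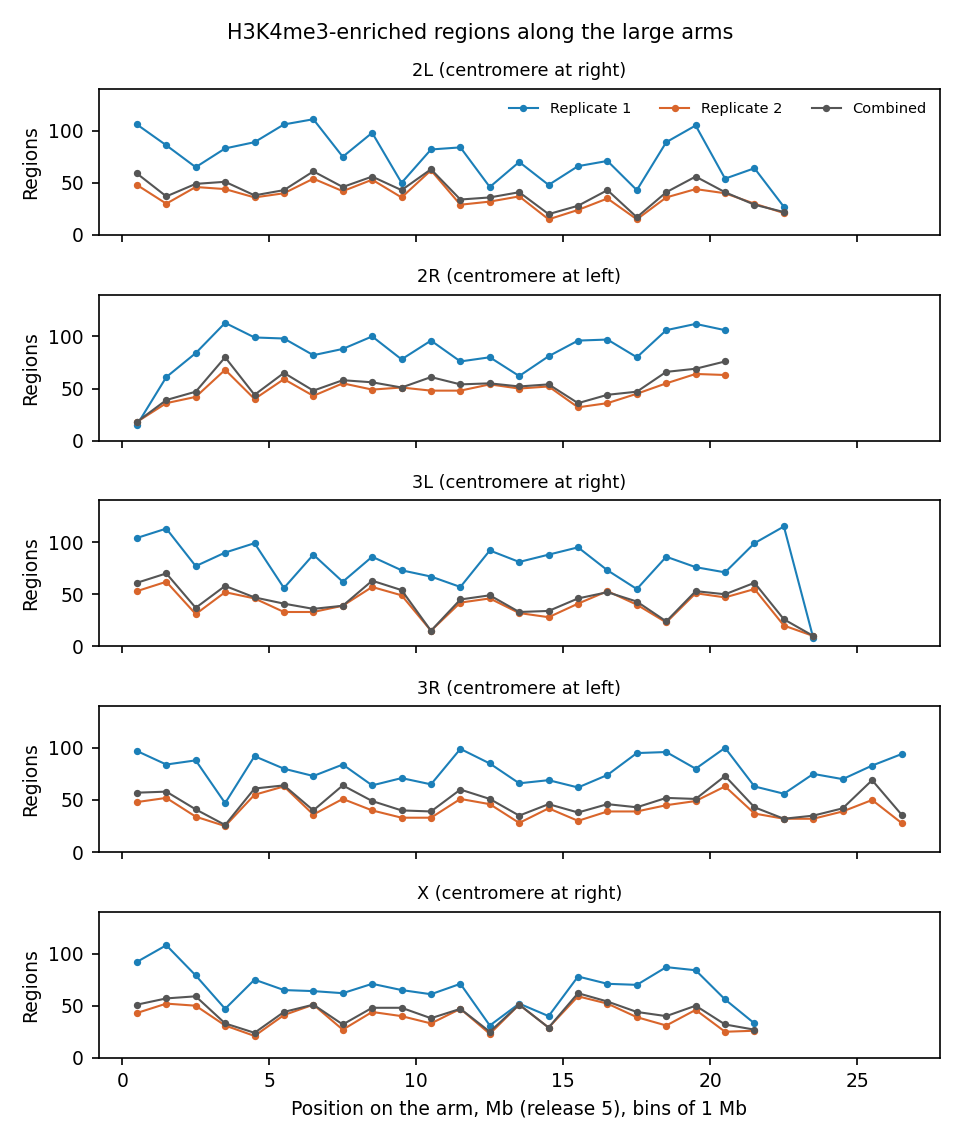
Number of enriched regions (y axis) in consecutive bins of 1 Mb along the 5 large arms (x axis, position in Mb on release 5), for replicate 1 (blue), replicate 2 (orange) and the combined list (grey); 1 point is 1 bin. Combined counts run from 10 at the centromere end of 3L to 80 on 2R.

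Sequence outside the 6 arms, which includes the heterochromatic scaffolds and unplaced sequence of release 5, held fewer regions per Mb than the arms. Across 48.3 Mb in 8 such sequences, the combined list had 77 regions, or 1.59 per Mb, against 45.4 per Mb on the arms. Unplaced sequence makes up most of that length: the 6 heterochromatic scaffolds alone (9.28 Mb) had 45 regions, or 4.85 per Mb. Unplaced sequence U had 32 regions, the heterochromatic scaffold of 3L had 13, that of 2R had 10, that of 3R had 9, the Y-chromosome scaffold had 6, that of X had 4 and that of 2L had 3. The short scaffold of X (0.204 Mb) had the highest density of these, at 29.4 per Mb in replicate 1 (6 regions) and 19.6 in replicate 2 (4 regions). Replicate 1 had 11 regions on U and replicate 2 had 30, although replicate 1 had the longer list. No region lay on the unplaced sequence Uextra (29.0 Mb) in any list, which by counting error allows up to 0.103 regions per Mb. How reads from repeated sequence were treated is not given in the sources used here.

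Broad regions of replicate 2 lay in sequence that replicate 1 also covered, whereas the broad regions of replicate 1 met replicate 2 at about the rate of shifted positions. The combined list had 648 regions of at least 5 kb (11.7%) and 36 of at least 10 kb. Replicate 1 had 140 regions of at least 10 kb, with a median score of 0.91 and a greatest width of 40684 bases, and replicate 2 had 28, with a median score of 2.90 and a greatest width of 18586 bases. All 28 broad regions of replicate 2 met a region of replicate 1, where shifts gave a mean of 61.7% of regions met (central 95% from 42.9% to 78.6%, two-sided permutation by shifts, p = 0.002). Of these 28, 21 met more than 1 region there. Replicate 1 covered 89.6% of their bases, against 80.1% of the bases of all regions of replicate 2. Of the 140 broad regions of replicate 1, 64 met a region of replicate 2 (45.7%, where shifts gave a mean of 46.7%, two-sided permutation by shifts, p = 0.861). Replicate 2 covered 13.5% of their bases, against 48.0% of the bases of all regions of replicate 1. Chains of regions less than 1 kb apart numbered 614 in the combined list, 1477 in replicate 1 and 500 in replicate 2. The median gap between neighbouring regions was 6936.5, 3669 and 7724 bases in the same order.

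The 5 highest scores of the combined list lay on 4 sequences, and all 5 regions were present in both replicates. The highest, 3.68, was on 2L from 8040226 to 8045203, with scores of 3.06 in replicate 1 and 3.99 in replicate 2. The next were on 3R from 25572626 to 25576728 (3.64), on 2R from 8211941 to 8215716 (3.55), on unplaced sequence U from 6383809 to 6386481 (3.52) and on 3R from 23404935 to 23410330 (3.51). The region on U had the highest score of replicate 2, 4.29, and a score of 1.96 in replicate 1. No gene annotation of release 5 was used, so it is not stated whether these positions are exonic, intronic or intergenic.

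The 5 widest combined regions lay on 2L, 2R and X. They ran from 4964784 to 4983361 on 2L (18578 bases), from 8054717 to 8072728 on 2R (18012 bases), from 508429 to 525596 on X (17168 bases), from 11986343 to 12003142 on 2L (16800 bases) and from 11480458 to 11495264 on X (14807 bases). Their scores lay between 1.61 and 2.64. In replicate 1 each was broken into 3 to 6 regions, and in replicate 2 into 1 or 2. The region on 2L from position 4964784 was the widest of replicate 2, at 18586 bases.

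The strongest regions found in a single replicate were all met by the combined list. In replicate 1 they were on 2L from 9984042 to 9995435 (score 1.33), on X from 15569272 to 15573717 (1.29), on X from 10500396 to 10501785 (1.25), on 3R from 25098228 to 25138911 (1.24) and on 3L from 5847609 to 5854783 (1.20). The region on 3R was the widest of that replicate, at 40684 bases, and met 8 regions of the combined list that together spanned 16199 bases. Scores of the combined regions that met these 5 reached 0.38 to 1.38. In replicate 2 they were on 3R from 21807794 to 21810207 (3.21), on U from 9710809 to 9712844 (2.65), on 2L from 5906174 to 5908900 (2.46), on 3L from 15150312 to 15153719 (2.41) and on 2L from 3870989 to 3873393 (2.39). These 5 were 2036 to 3408 bases wide, and the combined regions that met them had scores of 1.86 to 2.56. The region on 3R scored above 88.2% of the regions of replicate 2.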

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

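The result below was examined only after its values were seen. The combined list holds 10 regions typed as depleted. They are given because the comparisons of enriched regions leave them out; no test shows that their number is more than expected. Their scores lie between -0.16 and -0.01 and their widths between 1452 and 1816 bases. Each of the 10 meets a region typed as enriched in a replicate's own list: 4 in replicate 1 only, 5 in replicate 2 only and 1 in both. An example is the region on 3R from 6982215 to 6983906, which has the lowest score, -0.16, and meets an enriched region of replicate 1 only. The list of replicate 2 has 1 depleted region and that of replicate 1 has 0.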

How the results depend on the processing

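The 22 results were recomputed under their alternatives, which gave 123 values. The minimum width of 500 bases removed no region, so its 20 values test nothing. Of the others, 74 kept their direction and side of the threshold, or moved by less than the spread set for them. Among these 74, the share of bases covered in both replicates could not change under the overlap rules of 50%, since it counts bases whatever the rule. Keeping the upper 50% of scores gave 2769 combined regions of median width 3593 bases, a rho of 0.53 for scores and 0.77 for widths, 91.9% of combined regions met by replicate 1 and 83.9% by both, a ratio of 1.00 (0.996, exact binomial adjusted p = 0.941) on X and of 0.52 (adjusted p = 0.0096) on 4. Fewer regions and a narrower range of scores follow from that choice; for the other changes the cause was not tested. With reciprocal overlap of 50%, replicate 1 met 75.3% of combined regions and both replicates 71.6%. At equal numbers of regions these shares were 73.4% and 68.0%, replicate 2 met 92.7%, and the width difference of shared against unshared regions in replicate 1 turned to -10.5 bases (permutation test, adjusted p = 0.848). Replacing the combined list by that of either replicate gave 4959 to 9260 regions, median widths of 2296 to 2823 bases, 500 to 1477 chains and 573 to 946 regions of at least 5 kb, with the larger number of regions from replicate 1. The ratio on X then ran from 0.87 to 0.95 and lost its call in replicate 2's list, that on 4 from 0.62 to 0.87 and gained a call in replicate 1's list, and that on 3L from 0.96 to 1.02, which turned its direction in replicate 1's list; the call on 3L was also lost in the upper 50% of scores (exact binomial adjusted p = 0.119), in replicate 2's list (0.321) and in the intersection (0.250). The intersection of the replicates gave ratios (exact binomial tests) of 0.94 (adjusted p = 0.109) on X and 0.67 (adjusted p = 0.0346) on 4, and 280 regions of at least 5 kb. A bound of 3 kb gave 2367 broad regions and one of 10 kb gave 36. The excess on 2R kept its call under every list and score choice run. Counting depleted regions too, an alternative chosen after seeing the data and run for these values only, gave 5549 regions of median width 2750.0 bases. Comparisons with transcription start sites, genomic features, gene counts per arm and gene lists were not run. No paired analysis was possible because the Input samples have no list and the ChIP replicates form a single group. Depth per library is unknown, so it cannot be said which absences reflect depth.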

Other observations

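The predictions for most tests here were written before their results were seen. The exceptions, chosen after, are the comparisons of unmatched regions with the length of X and by arm, the tests of scores on X, and the values for score quartiles, broad regions and shifts of shared against unshared regions.

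A hypothesis that regions thin out in the 2 Mb next to the centromere was tested on the combined list. These stretches held 298 regions where 454.3 were expected from length, a ratio of 0.66 (exact 95% interval 0.59 to 0.73, exact binomial p = 6.2e-16, two-sided). Density there was 25.5 per Mb on 2L, 28.5 on 2R, 13.5 on 3L and 24 on X, against 43.0, 55.7, 45.4 and 44.3 on the rest of each arm. The right arm of chromosome 3 went the other way, with 57.5 against 46.8 per Mb. Without 3R the ratio was 0.51, and without each other arm it was 0.67 to 0.73. The binomial test takes regions as placed independently, so its p-value and interval are likely too sharp. Neither measures the spread between arms. Fewer genes and more repeats near centromeres may both contribute, and without gene positions or a measure of mappability neither was tested.

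A hypothesis that regions on chromosome 4 are wider than on the large arms was not borne out. Their median width was 2427 bases against 2774 bases, a difference of -347 bases (bootstrap 95% interval -554.1 to -157.9; permutation p = 0.0929). The interval lies wholly on the narrower side, but the permutation test did not reject equal medians. With 55 regions on 4, a narrower width there is not settled. Both replicates had the narrower median on 4, at 2110.5 against 2300 bases and 2589.5 against 2839 bases.

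Replicate 1 lists more regions, with a lower median score, than replicate 2. Wider regions at the same sites were not seen over matched pairs. The median width ratio there, replicate 1 over replicate 2, was 0.91 (bootstrap 95% interval 0.907 to 0.914). Such pairs keep 1 region where replicate 1 splits a site, and width alone would not add regions. The ratio therefore cannot decide why replicate 1 lists more of them. Outside the arms, replicate 1 listed only 49 regions, shared or not, on 48.3 Mb, or 1.01 per Mb, against 76.5 on the arms. These values argue against even scatter of the extra regions over all sequence, though how reads from repeated sequence were treated is not given. Whether the extra regions are scattered at random within the arms stays open. Of the extra regions, 12.25% lay within 2000 bases of a region of replicate 2, just below the 12.26% to 14.62% that shifts gave. This share meets neither bound set in advance. Their share on X was 14.7% (exact 95% interval 13.7% to 15.7%) against 18.6% of the length, but what scatter would give on X depends on its copy number, which is unknown. They numbered 39.7 to 41.7 per Mb on the 4 large autosomal arms, 30.2 on X and 21.5 on 4 (29 regions), and the second score quartile of replicate 1 met replicate 2 at the rate of the shifts (21.3% against 21.5%). Whether the list of replicate 1 merely reaches further down one ranking also stays open, since at equal numbers 71.5% of its regions met replicate 2, between the 80% and 60% set in advance as bounds. No biological explanation was tested, since the design compares no groups here.

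Replicate 1 also has a smaller share of its regions on X, at 16.1% (Wilson 95% interval 15.4% to 16.9%) against 17.7% (16.7% to 18.8%) in replicate 2 (Fisher's exact test over regions, two-sided p = 0.0155). Fisher's test takes the 2 lists as independent samples, although 87.3% of the regions of replicate 2 met replicate 1. Its p ignores that pairing and does not measure the gap between the lists. The unmatched regions of replicate 1 are poorer in X than its matched regions by 2.94 percentage points (a difference of -2.94, 95% interval -4.44 to -1.44). Matched regions follow replicate 2, so this difference nearly restates the gap and does not show its cause, and weak regions of replicate 1 alone stay open as an explanation. Of the regions of replicate 2 on X, 86.4% met replicate 1 (Wilson 95% interval 83.9% to 88.5%), against 87.2% to 89.1% on the other 4 large arms. Lower scores throughout X in replicate 1 were not seen: the median change of rank percentile on X minus that on autosomal arms was 0.58 points (bootstrap 95% interval -0.63 to 2.51), which leaves small shifts either way open. No biological explanation was tested, since both replicates have the same stage and genotype.

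Regions on X have higher scores than those on the autosomal arms in each list. The median was 1.72 against 1.52 in the combined list (permutation p = 0.00901, adjusted p = 0.018 over 10 tests), 0.71 against 0.62 in replicate 1 (adjusted p = 5e-05) and 2.37 against 2.19 in replicate 2 (adjusted p = 0.0238). Whether fewer weak regions are listed on X stays open. Combined regions on X were 0.88 times the number expected from length in the lower 50% of scores (exact 95% interval 0.80 to 0.95) and 0.996 times in the upper 50% (0.92 to 1.08), but with a ratio of 0.94 overall and higher scores on X, a split of this kind has to come out so and gives no support. Within that upper 50% the median on X was still higher, at 2.42 against 2.35 (difference 0.06, bootstrap 95% interval 0.01 to 0.12). This split of the scores replaced an earlier test over matched regions, where the difference was 0.12 in replicate 1 (bootstrap 95% interval 0.06 to 0.17) and 0.19 in replicate 2 (0.07 to 0.29). Matched regions still include weak ones, so that test cannot separate the explanations either. Median widths on X were larger in the combined list, at 2885.5 against 2742 bases (permutation test, adjusted p = 0.00897), but not detectably so in replicate 1 (adjusted p = 0.719) or replicate 2 (adjusted p = 0.0943). The copy number of X, which depends on the sex of the embryos (not given in the labels), its treatment through the Input, and a higher level of the mark on X also stay open, and none of these was tested.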
